A study of Danio rerio with 4 samples.

How the data were processed

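Liver RNA of zebrafish at 26 °C (replicates 2 and 3) and 34 °C (replicates 1 and 2), day 4, was compared on 4 Agilent 2-colour arrays, per the labels. Per the labels' protocols, RNA was extracted with Trizol and labelled by Agilent's 2-colour procedure, and per the series' design text each sample was labelled once with each dye around a loop. The replicates are biological replicates per the design text, and from how many fish each came is not given in the sources used here, nor is their sex.

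The deposited values are log2 ratios, 1 per probe and array. Every array's median lies close to 0, so they were likely normalised within arrays before deposit, though this is not stated. limma is named in the submitters' processing notes without a version. The within-array method, background correction, spot filters and whether arrays were scaled to each other are not given in the sources used here. The log base is not stated: the largest absolute value, 6.50, exceeds 4.82, the base 10 logarithm of the 16-bit scanner maximum, and base 2 is limma's convention. The direction of each ratio, Cy5 over Cy3, was taken from the dye labels, titles, design text and limma's convention and is likely, not stated. Arrays of opposite orientation correlated negatively over probes (r = −0.433, −0.373, −0.138 and −0.67) and arrays of the same orientation positively (0.319 and 0.329); probes are not independent replicates, and each such pair of opposite arrays also shares a sample. No spot intensities were used here, so dim probes were not filtered, the signal over background behind a value is unknown, and precision is limited by the number of arrays. No value was missing on any of the 43603 probes.

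Probes were named through the platform annotation. A single gene symbol was given for 23717 probes (54.4%), several symbols for 0, and 19886 probes stayed unnamed here. An Entrez identifier matched the gene table (GRCz12tu, used for names only) for 23534 probes (99.2%), and 0 symbols had to be updated. The mean over a gene's probes gave 15554 genes. Of 6104 genes with more than 1 probe, 2442 had probes whose differences had both signs.

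The levels of the 4 biological samples were solved per gene from the 4 log ratios by least squares (MASS 7.3.60.0.1), relative to their mean. A constant dye effect cancels in this step. The sum of the 4 ratios around the loop, divided by 2, holds the dye effect and technical error and had a standard deviation of 0.234 over genes. The 34 °C and 26 °C samples were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes, 2 residual degrees of freedom, 1.69 prior degrees of freedom) and Benjamini-Hochberg adjustment at 0.05. Errors of differences are limma's standard errors, except in the tests of carry-over, scaling and response size. There they are bootstrap standard errors from 2000 resamplings of the genes of a list. For a single gene tested exactly, 2 samples against 2 cannot give a two-sided exact p below 0.333, so limma's shared estimate of the spread carries the test. The 29 gene lists covered chaperones, metabolism, translation, cell cycle, hormones, liver functions and markers of other cell types, and were fixed before the data were examined. They were tested with camera at a preset correlation of 0.01 and adjusted over the 29 lists. Some lists hold members beyond their name, since they were built from symbol patterns. Median, mean and test had the same sign for every list.

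Genes named in the report followed a rule fixed before the data were examined. It took up to 12 genes per direction with the largest difference among those past the threshold with 1 sign on all 4 arrays, filled up from genes with an unadjusted p under 0.05, and up to 4 members per list with the smallest p, leaving out clone identifiers. As 0 genes passed, all 24 came from the filling step. The genes of hsp70l, hsp70.3, hsp90aa1.1, cirbpa, cirbpb and fabp10a are given whatever their value, and vtg1 was not analysed here because no probe carried that name. Other members that passed 0.05 adjusted over their list alone were added after their values were seen.

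The procedure was tested on simulated data for this comparison with 15554 genes, 100 of them changed by 1 and 100 by 2 log2 units. With spread placed between biological samples, 56% and 81% were recovered at adjusted p 0.05, and 5.0% of unchanged genes had an unadjusted p under 0.05. With spread placed between arrays, 61% and 88% were recovered and the share was 2.0%, so the fit is conservative where array error dominates. A fit with arrays as units and a dye term gave 11.6% and 5.36%. The changed genes were drawn without regard to their spread. In the data some of the largest differences had wide standard errors, such as 1.13 for hsp70.3 and 0.81 for vtg3, against 0.08 for hspa5. The recovered shares may thus be too high for such genes. A simulated list of 40 genes shifted by 0.5 was called and 0 of the other lists were. The simulated genes were independent, so this does not test false calls where members of a list are correlated. In the data the estimated correlation ran from −0.04 for the erythrocyte list to 0.89 for the ovary and germ cell list.

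Alternatives covered arrays as units with and without a dye term, centring and scaling of arrays, 1 probe per gene, leaving out the 10% of probes with the largest loop sum, robust empirical Bayes, other thresholds, probes counted in place of genes, an estimated correlation for the lists, and leaving out each sample or array in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.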

Results

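Transcripts of zebrafish (Danio rerio) liver were measured at 26 °C and at 34 °C on day 4 of a temperature experiment that the submitters ran while a custom array was being made. The labels describe 4 biological samples, which are replicates 2 and 3 at 26 °C and replicates 1 and 2 at 34 °C. Total RNA of each sample was hybridised on 2 of 4 Agilent 2-colour arrays, once labelled with Cy5 and once with Cy3, in a loop in which every array held 1 sample of each temperature. The values were log2 ratios of 43603 probes per array, and their medians lay at 0.0036, 0.0023, 0.0039 and 0.00091. Their standard deviations were 0.275 and 0.328 on the arrays that joined 34 °C replicate 1 to 26 °C replicates 2 and 3, and 0.359 and 0.366 on those that joined 34 °C replicate 2 to 26 °C replicates 3 and 2. The number of arrays limits the precision. The direction of the ratios, Cy5 over Cy3, is likely from the dye labels, the array titles and the design text, and all signs given here would turn if it were the inverse.

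The comparison asked which liver transcripts differed between 34 °C and 26 °C. Of the gene lists, those of heat shock proteins and of endoplasmic reticulum chaperones had median log2 differences of 0.28 and 0.49 at 34 °C from 26 °C, and those of fatty acid oxidation and of egg yolk precursors −0.47 and −0.41. In that direction, 25 of 63, 22 of 44, 15 of 32 and 7 of 26 members had an unadjusted p under 0.05. These 4 lists passed camera at a preset correlation between genes, and 0 of them did with an estimated correlation (adjusted p = 0.61, 0.61, 0.69 and 0.71). The estimated setting also leaves the test only 2 degrees of freedom, so correlation between genes is not the sole reason. The median of the egg yolk list turned to 0.17 without 34 °C replicate 2, and adjusted over the list alone 0 of its members passed. Of its members, 17 code for egg coat proteins, with medians of 0.57 in 34 °C replicate 1 and 0.01 and 0.43 at 26 °C. Its 5 vitellogenins did not turn, with medians of −0.37 in 34 °C replicate 1 and 1.09 and 0.95 at 26 °C. The transcript of hsp70.3, a stress-inducible Hsp70 chaperone, had the largest positive difference among the named genes, with a 13.6-fold higher ratio at 34 °C (log2 difference 3.77 ± 1.13, SE, 2 samples per temperature). That of vtg3, a vitellogenin from which egg yolk is made, had the largest negative difference (log2 difference −3.32 ± 0.81, a 10-fold higher ratio at 26 °C). The most even difference among the largest was that of hspa5 (BiP, the main Hsp70 of the endoplasmic reticulum), whose levels relative to the 4-sample mean were −1.13 and −1.04 at 26 °C and 1.02 and 1.15 at 34 °C.

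Across 15554 genes, 0 passed an adjusted p of 0.05 in limma with samples as units and Benjamini-Hochberg adjustment, and the lowest adjusted p was 0.104, shared by 37 genes. At an unadjusted p under 0.05 there were 1535 genes, 881 higher and 654 lower at 34 °C, where chance alone gives 777.7. Of the 1535, 1449 had the same sign on all 4 arrays, and 97 were over 2-fold higher and 67 over 2-fold lower at 34 °C. The 2 groups did not overlap for 5362 genes (34.5%), against 33.3% by chance. With the 4 arrays as units and a dye term, limma called 148 genes at adjusted p 0.05, 96 higher and 52 lower, but that fit takes arrays that share a sample as independent. Leaving out 34 °C replicate 1 moved the counts at an unadjusted p under 0.05 to 1491 higher and 1211 lower genes, and leaving out 26 °C replicate 2 or replicate 3 moved them to 497 and 373 or to 489 and 425.

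Between single samples, the spread was wider at 34 °C than at 26 °C. Over genes, the difference between 34 °C replicates 2 and 1 had a standard deviation of 0.381, with 394 genes apart by over 1 log2 unit. The difference between the 26 °C samples had a standard deviation of 0.212 with 77 such genes. The difference between the temperatures, taken between means of 2 samples, had 0.277 with 204. Means vary less than single samples, so the temperature value is not directly comparable with the gaps between replicates. The same limit holds for the median absolute difference. It was 0.063 between the temperatures, 0.087 between the 26 °C samples and 0.105 between the 34 °C samples. Genes used as intestine markers had median levels of −0.64 and 0.10 in 26 °C replicates 2 and 3, −0.88 in 34 °C replicate 1 and 1.26 in 34 °C replicate 2. Genes used as ovary and germ cell markers had medians of −0.04 and 0.34 in 26 °C replicates 2 and 3, 0.26 in 34 °C replicate 1 and −0.73 in 34 °C replicate 2.

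Among the 12 largest positive differences, 7 more genes besides hsp70.3 and hspa5 code for chaperones or cofactors of the same 2 systems or for the collagen chaperone. The genes of hsp90aa1.2, an Hsp90 of the cytosol, and hsc70, an Hsp70, were higher by 3.47 ± 0.52 and 2.54 ± 0.48 on the log2 scale. The genes of hspa4a, an Hsp110-type exchange factor for Hsp70, and hsp70l, a stress-inducible Hsp70, were higher by 2.49 ± 0.17 and 2.48 ± 0.30. The genes of serpinh1b (Hsp47, a collagen chaperone), hyou1 and hsp90b1 (Grp170 and Grp94 of the endoplasmic reticulum) were higher by 2.16 ± 0.21, 2.12 ± 0.11 and 2.09 ± 0.13. The other genes of this set were cbsb, a cystathionine beta-synthase of transsulfuration (2.47 ± 0.28), aldoab, an aldolase (2.35 ± 0.56), and gja13.1, a connexin (2.11 ± 0.18). In 34 °C replicate 2 the level of hsp70.3 was 3.41 and in replicate 1 it was 0.36, against −1.75 and −2.01 in the 26 °C samples, so the size of its difference rests on 34 °C replicate 2, without which it was 2.24. The difference of hsp90aa1.2 was 1.82 with noisy probes, those with the largest sum of ratios around the loop, left out. The gene of aldoab showed the opposite order, with 1.92 in 34 °C replicate 1 and 0.43 in replicate 2.

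Among the 12 largest negative differences under the same rule, 4 were vitellogenins. Besides vtg3, the log2 differences were −2.14 ± 0.34 for vtg5, −1.96 ± 0.45 for vtg4 and −1.94 ± 0.55 for vtg2. The gene of nots (nothepsin, an aspartic protease of the liver of female fish) differed by −2.30 ± 0.63. The sizes for nots and vtg2 rest on 34 °C replicate 2, without which they were −1.46 and −1.21. That of vtg3 also rests in part on it, with levels of −0.56 and −2.76 in 34 °C replicates 1 and 2. Its levels in 26 °C replicates 2 and 3 were 1.59 and 1.73. Enzymes of lipid metabolism were elovl2, an elongase of polyunsaturated fatty acids (−2.40 ± 0.13), cpt1b, a carnitine palmitoyltransferase that admits fatty acids to mitochondria (−2.11 ± 0.24), and msmo1, a sterol oxidase of cholesterol synthesis (−1.77 ± 0.21). The rest were cyp2k6, a cytochrome P450 (−2.36 ± 0.25), rab1aa, a Rab GTPase (−2.29 ± 0.21), zbtb24, a zinc finger protein (−2.05 ± 0.30), and rdh8a, a retinol dehydrogenase (−1.96 ± 0.41). The vitellogenins and the Hsp70 paralogs are families of similar sequence, so probes can take up transcripts of a related gene and the share of each member is uncertain.

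**Figure D1:**
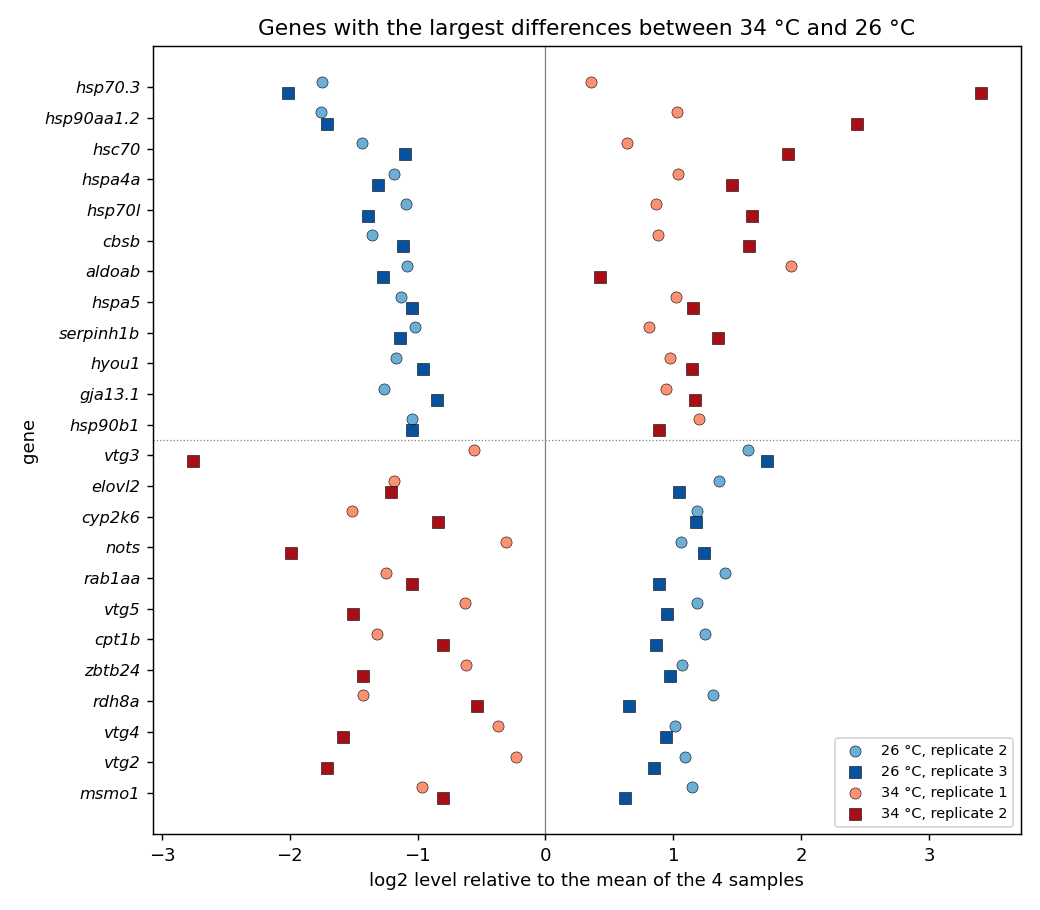
Levels of 24 genes (rows) in each of the 4 biological samples (symbols), on a log2 axis relative to the mean of the 4 samples. They had the largest differences among genes with an unadjusted p under 0.05 and 1 sign on all 4 arrays. As this rule left out genes whose arrays disagreed in sign, the separation of the temperatures is partly its product. The 12 upper genes were higher at 34 °C and the 12 lower ones were lower; hsp70.3 lay at 0.36 and 3.41 in the 34 °C samples, and vtg3 at −0.56 and −2.76.

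The 29 gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists, and 15 passed an adjusted p of 0.05, 7 higher and 8 lower at 34 °C. With a correlation estimated from the 4 samples, 0 lists passed, also at an unadjusted p under 0.05, and each such adjusted p stands beside its list. The estimated setting also tests on the 2 residual degrees of freedom, fewer than the preset one. Lists with an estimated correlation below 0.01 did not pass it either, such as erythrocyte markers (−0.04) and fatty acid synthesis (−0.02). The failure is thus not due to correlation between genes alone. A call is said to be lost where the list no longer passed at the preset correlation in another setting. Some settings left out 1 array, of which 2 had the 34 °C sample in Cy5 and 2 in Cy3. In every list, 0 members passed when adjusted over all genes, so members are said to have risen or fallen where they passed 0.05 adjusted over the list alone.

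Heat shock proteins and cytosolic or mitochondrial chaperones rose as a list (median log2 difference 0.28, camera adjusted p = 3.08e-13, adjusted p = 0.61 with an estimated correlation). Of 63 measured members, 25 were higher and 1 lower at an unadjusted p under 0.05, and adjusted over the list alone 21 rose and 1 fell. The Hsp90 cochaperone gene fkbp4 rose by 1.33 ± 0.09 and hspa14, an Hsp70 of the cytosol, by 1.06 ± 0.07. The mitochondrial chaperonin genes hspd1 (Hsp60) and hspe1 (Hsp10) rose by 0.83 ± 0.11 and 2.04 ± 0.33, the Hsp90 cochaperone genes stip1 and ahsa1b by 1.34 ± 0.21 and 0.98 ± 0.19, and the chaperonin subunit gene cct6a by 0.63 ± 0.11. The member that fell was hspb6, a small heat shock protein, at −0.44 ± 0.06. Another cytosolic Hsp90 gene, hsp90aa1.1, differed by 0.06 ± 0.08, with probes of both signs, and by −0.01 without 34 °C replicate 2. A further one, hsp90ab1, differed by 0.33 ± 0.23. The list's medians were −0.13 and −0.16 in the 26 °C samples, 0.06 in 34 °C replicate 1 and 0.22 in 34 °C replicate 2, the sample with the highest intestine markers. Without 34 °C replicate 2 the median difference was 0.17 (adjusted p = 3.08e-10).

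Endoplasmic reticulum chaperones and the unfolded protein response rose as a list (median 0.49, camera adjusted p = 3.08e-13, adjusted p = 0.61 with an estimated correlation). Adjusted over the list alone, 22 of 44 members rose and 3 fell, the same counts as at an unadjusted p under 0.05. Besides hspa5, hyou1 and hsp90b1, the genes of the cofactors dnajb9b, dnajc3b and sdf2l1 rose by 1.32 ± 0.09, 1.6 ± 0.20 and 1.51 ± 0.15, and manf, a secreted stress-induced protein, by 1.89 ± 0.19. The lectin chaperone genes calr3b and canx (calreticulin and calnexin) rose by 1.65 ± 0.25 and 0.78 ± 0.15, and the disulfide isomerase genes pdia3 and pdia4 by 0.73 ± 0.07 and 1.17 ± 0.26. Genes of the degradation pathway of this compartment, herpud1, syvn1 and derl2, rose by 1.15 ± 0.26, 0.97 ± 0.15 and 0.41 ± 0.08, and atf4a, a transcription factor of the stress response, by 0.87 ± 0.10. The list's other transcription factor genes, atf4b, atf6, xbp1 and ddit3, did not pass an unadjusted p of 0.05. They differed by 0.30 ± 0.32, 0.15 ± 0.07, −0.06 ± 0.14 and 0.10 ± 0.09. The 3 members that fell, ssr2, ssr3 and ssr4 (−0.75 ± 0.18, −0.67 ± 0.06 and −0.33 ± 0.09), code for subunits of the translocon-associated protein complex, which assists the channel through which nascent chains enter the compartment.

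Mitochondrial and peroxisomal fatty acid oxidation fell as a list (median −0.47, camera adjusted p = 6.50e-09, adjusted p = 0.69 with an estimated correlation). Of 32 members, 15 were lower and 2 higher at an unadjusted p under 0.05, and 4 fell adjusted over the list alone. These were cpt1b, the peroxisomal thiolase acaa1 (−1.02 ± 0.13), the enoyl-CoA isomerase eci1 (−0.84 ± 0.10) and the peroxisomal dienoyl-CoA reductase decr2 (−1.15 ± 0.17). The list's medians were 0.40 and 0.08 in 26 °C replicates 2 and 3, and −0.38 and −0.09 in 34 °C replicates 1 and 2. Without 34 °C replicate 2 or 26 °C replicate 3 the median difference was −0.77 or −0.67. Without 34 °C replicate 1 or 26 °C replicate 2 it was −0.33 for both.

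Fatty acid synthesis, desaturation and elongation had a median of −0.04 and fell as a list (camera adjusted p = 0.0231, adjusted p = 0.61 with an estimated correlation). Of 45 members, 7 were lower and 0 higher at an unadjusted p under 0.05, and adjusted over the list alone elovl2 and the desaturase gene fads2 (−1.42 ± 0.13) fell. The genes of chka, a choline kinase, and aclya, an ATP citrate lyase, differed by −0.79 ± 0.14 and −0.40 ± 0.08, and chka by −1.33 with 1 probe per gene. The call was lost with noisy probes left out (median −0.01, adjusted p = 0.0738) and without either array that had 34 °C in Cy5 (median −0.04, adjusted p = 0.102 and 0.077). Without 34 °C replicate 1 the median was −0.10, and without 26 °C replicate 3 it was −0.02. Sterol synthesis and uptake did not pass (28 members, median −0.05, camera adjusted p = 0.0683). In it msmo1 fell adjusted over the list alone, tm7sf2, a sterol reductase, differed by −0.88 ± 0.14, and the receptor gene ldlrb and the reductase gene hmgcrb by 0.92 ± 0.20 and 0.41 ± 0.09. Without either array that had 34 °C in Cy5 tm7sf2 differed by −0.45, and without either that had 26 °C in Cy5 hmgcrb by 0.26. The sterol list passed without 26 °C replicate 3 (median −0.11, adjusted p = 0.00163), without 34 °C replicate 1 (median −0.18, adjusted p = 0.0119) and without the array of 26 °C replicate 3 over 34 °C replicate 2 (adjusted p = 0.0496). It did not pass without 26 °C replicate 2, where its median was −0.08 (adjusted p = 0.0972).

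Estrogen response and egg yolk precursors fell as a list (26 members, median −0.41, camera adjusted p = 2.75e-04, adjusted p = 0.71 with an estimated correlation). At an unadjusted p under 0.05, 7 members were lower and 0 higher, and adjusted over the list alone 0 passed. The list held 5 vitellogenins with a median difference of −1.96 and 17 genes of egg coat proteins (zona pellucida type) with a median of −0.39, and the estrogen receptor gene esr1 differed by −1.34 ± 0.25. The 5 vitellogenins had medians of 1.09 and 0.95 in 26 °C replicates 2 and 3, −0.37 in 34 °C replicate 1 and −1.59 in 34 °C replicate 2. The egg coat genes had medians of 0.01 and 0.43 at 26 °C, 0.57 in 34 °C replicate 1 and −1.0 in 34 °C replicate 2, which also had the lowest oocyte markers, a list that shares 8 genes with this one. Without 34 °C replicate 2 the list's median turned to 0.17 (adjusted p = 0.819), and without 34 °C replicate 1, 26 °C replicate 2 or 26 °C replicate 3 it was −1.27, −0.65 or −0.24.

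Cell cycle and DNA replication fell as a list (56 members, median −0.24, camera adjusted p = 1.79e-04, adjusted p = 0.76 with an estimated correlation), though 0 members differed at an unadjusted p under 0.05. The genes with the lowest p were cdk1, the kinase of mitotic entry (−0.41 ± 0.16), the kinetochore motor cenpe (−0.61 ± 0.25), the clamp loader subunit rfc3 (−0.32 ± 0.13) and the mitotic activator cdc20 (−0.49 ± 0.24). Without 26 °C replicate 3 cdk1, cenpe and cdc20 differed by −0.23, −0.35 and −0.25. The differences of cenpe, rfc3 and cdc20 without 34 °C replicate 2 were −0.40, −0.16 and −0.28. Its sample medians, −0.05 and 0.29 at 26 °C and 0.11 and −0.39 at 34 °C, had the order of the oocyte markers. The call was lost without 26 °C replicate 3 (median −0.07, adjusted p = 0.337) and without 34 °C replicate 2 (median −0.01, adjusted p = 0.978), and the median was −0.54 without 34 °C replicate 1 and −0.44 without 26 °C replicate 2. The ovary and germ cell markers themselves fell as a list (30 members, median −0.31, camera adjusted p = 0.0259, adjusted p = 0.81 with an estimated correlation), with 0 members past an unadjusted p of 0.05. The germ cell genes ddx4 (Vasa) and dazl differed by −0.18 ± 0.07 and −0.71 ± 0.42, and the oocyte factor figla and the meiotic gene sycp3 by −0.29 ± 0.15 and 0.09 ± 0.06. The difference of dazl was −0.22 without 34 °C replicate 2, −0.44 without 26 °C replicate 3 and −1.21 without 34 °C replicate 1. That of figla was −0.10 without 26 °C replicate 3 and −0.48 without 26 °C replicate 2. That of ddx4 turned to 0.01 without either array that had 34 °C in Cy5. Without either that had 26 °C in Cy5 the difference was −0.37 for ddx4 and 0.05 for sycp3. Without 34 °C replicate 2 this list's median was 0.11 and it passed in the other direction (adjusted p = 0.0237), and without 26 °C replicate 3 it was −0.05 (adjusted p = 0.398). The call was also lost with noisy probes left out (adjusted p = 0.0738) and without either array that had 34 °C in Cy5 (median −0.14, adjusted p = 0.0852 and 0.079). The median was −0.89 without 34 °C replicate 1 and −0.51 without 26 °C replicate 2.

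Cytosolic ribosomal proteins fell as a list (71 members, median −0.21, camera adjusted p = 3.43e-08, adjusted p = 0.69 with an estimated correlation). Of these, 10 were lower and 4 higher at an unadjusted p under 0.05, and adjusted over the list alone rpl22l1 fell (−0.66 ± 0.06). The genes rpl5a and rpl12 differed by −0.56 ± 0.08 and −0.34 ± 0.06 and rpl31 by 0.65 ± 0.12. The difference of rpl12 was −0.11 without either array that had 34 °C in Cy5 and −0.57 without either that had 26 °C in Cy5. The sample medians were 0.04 and 0.15 at 26 °C, 0.02 in 34 °C replicate 1 and −0.23 in 34 °C replicate 2, the sample with the lowest oocyte markers. The median was −0.10 without 34 °C replicate 2 and −0.37 without 34 °C replicate 1 (adjusted p = 0.0428 and 2.21e-13). The call was lost without the array of 26 °C replicate 2 over 34 °C replicate 1 and without that of 26 °C replicate 3 over 34 °C replicate 2 (median −0.05 for both, adjusted p = 0.0788 and 0.243). Translation factors and aminoacyl-tRNA synthetases rose as a list (88 members, median 0.05, camera adjusted p = 0.0296, adjusted p = 0.61 with an estimated correlation), with 18 higher and 8 lower at an unadjusted p under 0.05. Adjusted over the list alone, the initiation factor genes eif4ba, eif4g1a, eif3jb and eif4e1c rose (0.57 ± 0.07, 0.40 ± 0.06, 0.61 ± 0.09 and 1.17 ± 0.17), while eif4e3 and eif5a2 fell (−1.0 ± 0.13 and −0.74 ± 0.11). The difference of eif4g1a was 0.11 with noisy probes left out, 0.69 with 1 probe per gene and 0.21 without either array that had 26 °C in Cy5. This call was lost without 26 °C replicate 2 (median 0.05, adjusted p = 0.0587) and without 34 °C replicate 2 (median 0.08, adjusted p = 0.231), where the median was no smaller. It was also lost without either array that had 26 °C in Cy5 (median 0.03, adjusted p = 0.137 and 0.268). Without 34 °C replicate 1 the median was 0.10, and the highest in the 15 settings that kept the preset correlation was 0.17.

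Cold-inducible RNA-binding and high mobility group proteins fell as a list (17 members, median −0.05, camera adjusted p = 0.0264, adjusted p = 0.69 with an estimated correlation). Adjusted over the list alone, cirbpa, a cold-inducible RNA-binding protein, and the chromatin proteins hmgb3a and hmgb2a fell (−0.64 ± 0.06, −0.77 ± 0.08 and −0.71 ± 0.13), and the splicing regulator rbmx rose (0.50 ± 0.11). The paralog cirbpb differed by 0.16 ± 0.20, with probes of both signs, and by −0.09 without 34 °C replicate 2. It also differed by −0.27 without either array that had 26 °C in Cy5 and by 0.60 without either that had 34 °C in Cy5. At an unadjusted p under 0.05, 5 members were lower and 1 higher. The call was lost without 34 °C replicate 1 (median −0.07, adjusted p = 0.447), with noisy probes left out (median −0.02, adjusted p = 0.428) and with arrays as units and no dye term (adjusted p = 0.0796). It was also lost without either array that had 34 °C in Cy5 (median −0.02, adjusted p = 0.851 and 0.496), where cirbpa differed by −0.33. The median was −0.23 without 34 °C replicate 2 and −0.17 without 26 °C replicate 2, and the lowest in the 15 settings that kept the preset correlation was −0.27.

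3 lists of energy metabolism passed with small median rises. In 26 °C replicates 2 and 3 and 34 °C replicates 1 and 2, the citrate cycle list had medians of −0.04, −0.02, −0.008 and 0.12. Those of glycolysis were −0.03, −0.05, −0.01 and 0.14. Both stood apart only in 34 °C replicate 2, the sample with the highest intestine markers. Oxidative phosphorylation had −0.03, −0.02, 0.10 and −0.05. Oxidative phosphorylation (82 members, median 0.03, camera adjusted p = 0.0435, adjusted p = 0.69 with an estimated correlation) had 12 higher and 3 lower members at an unadjusted p under 0.05. In it the ATP synthase subunit gene atp5pf and the Rieske protein gene uqcrfs1 rose adjusted over the list alone (1.2 ± 0.07 and 0.70 ± 0.06), and the complex I subunit genes ndufa1 and ndufa3 differed by 0.90 ± 0.13 and 0.71 ± 0.11. The gene ndufa3 differed by 0.44 without either array that had 34 °C in Cy5. The call was lost in 9 of 15 settings that kept the preset correlation. The adjusted p was 0.055 and 0.0675 for arrays as units with and without a dye term, 0.0703 for arrays centred and scaled, 0.0788 for 1 probe per gene and 0.245 for noisy probes left out, where the median was 0.003. It was 0.998 and 0.496 without either array that had 34 °C in Cy5 (median 0.0029) and 0.0806 without 26 °C replicate 3 (median 0.06). The median turned to −0.03 without 34 °C replicate 1 (adjusted p = 0.956). The median was 0.10 without 34 °C replicate 2 and 0.06 without 26 °C replicate 2. The citrate cycle and pyruvate dehydrogenase (31 members, 6 higher and 1 lower, median 0.07, camera adjusted p = 0.0496, adjusted p = 0.69 with an estimated correlation) held pdhx, a pyruvate dehydrogenase component, which rose adjusted over the list alone (0.89 ± 0.07), and the succinate dehydrogenase gene sdhb (0.60 ± 0.11). Its call was lost without 26 °C replicate 2, 26 °C replicate 3 or 34 °C replicate 2 (medians 0.05, 0.09 and 0.02, adjusted p = 0.0737, 0.109 and 0.71). It was also lost with arrays as units and a dye term (adjusted p = 0.0623), with arrays centred on their medians (0.0518) and without either array that had 26 °C in Cy5 (median 0.03, adjusted p = 0.351 and 0.446). Its median was 0.17 without 34 °C replicate 1. Glycolysis and gluconeogenesis (38 members, 4 higher and 1 lower, median 0.08, camera adjusted p = 0.0215, adjusted p = 0.69 with an estimated correlation) had 0 members past 0.05 adjusted over the list alone. The enolase gene eno3 differed by 0.62 ± 0.08, and the lactate dehydrogenase genes ldhba and ldhbb by 0.83 ± 0.18 and −1.29 ± 0.30. That call was lost without 26 °C replicate 3 (median 0.07, adjusted p = 0.0806), without 34 °C replicate 2 (median 0.06, adjusted p = 0.262) and without either array that had 26 °C in Cy5 (median 0.04, adjusted p = 0.101 and 0.219). The median was 0.17 without 34 °C replicate 1.

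**Figure D2:**
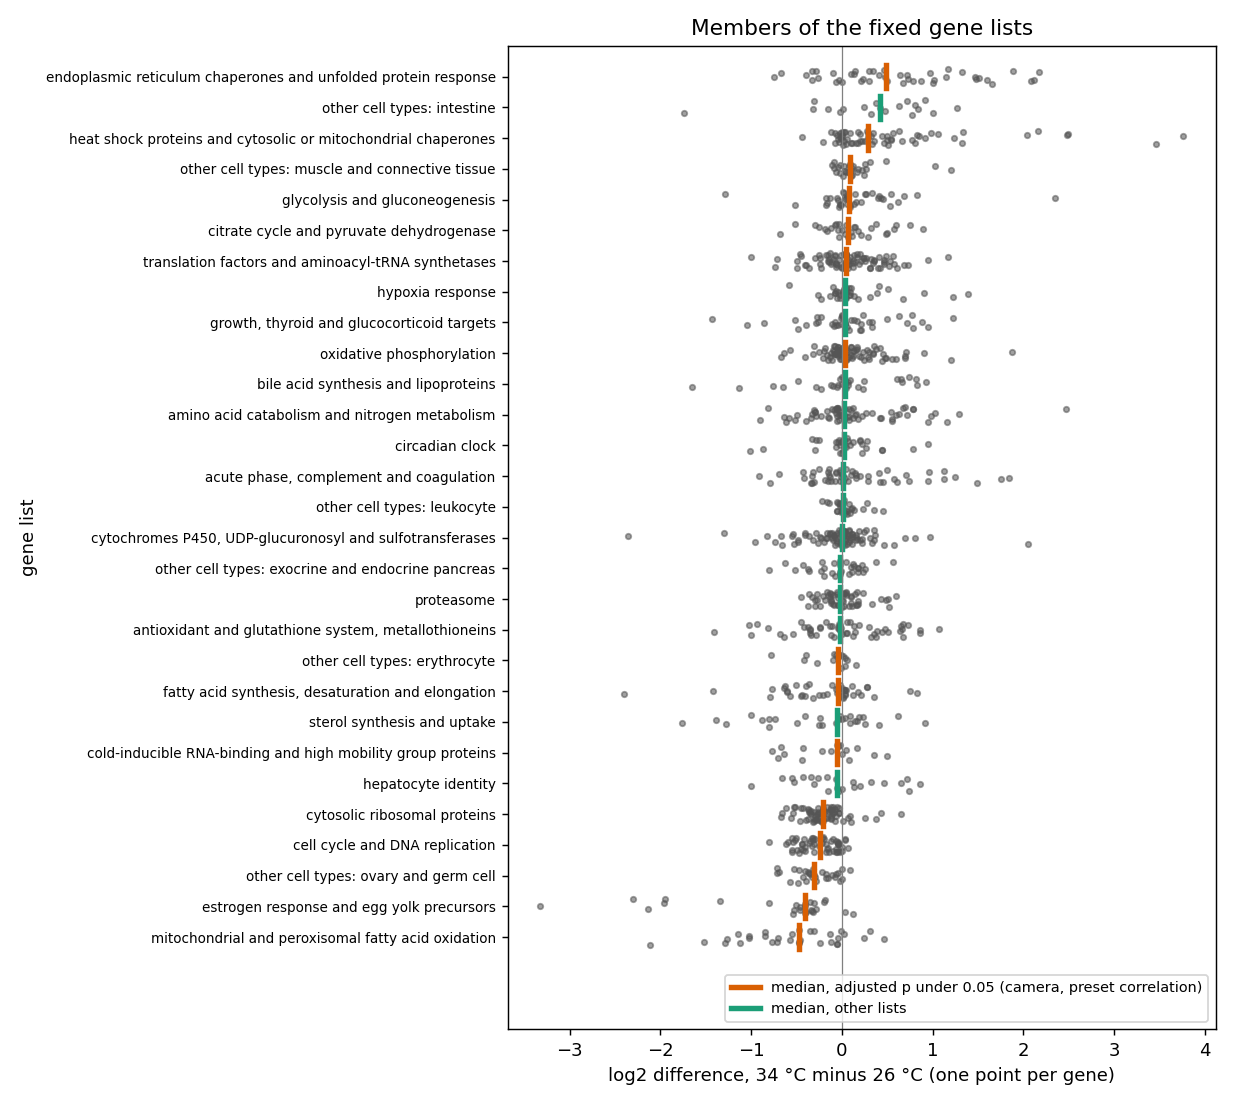
Log2 difference between 34 °C and 26 °C (horizontal axis) of each measured member (grey points) of the 29 gene lists (rows), with the median as a bar, orange where camera's adjusted p was under 0.05 at the preset correlation. The medians ran from −0.47 for fatty acid oxidation to 0.49 for endoplasmic reticulum chaperones.

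Amino acid catabolism and nitrogen metabolism did not shift as a list (68 members, median 0.02, camera adjusted p = 0.278), but 7 members rose and 1 fell adjusted over the list alone, and 11 were higher and 9 lower at an unadjusted p under 0.05. The transsulfuration genes cbsb, cbsa and cth rose by 2.47 ± 0.28, 1.03 ± 0.15 and 1.16 ± 0.12, and bhmt, which remethylates homocysteine, by 0.95 ± 0.07. The aminotransferase genes agxtb and got2b rose by 1.29 ± 0.15 and 0.72 ± 0.08 and dbt, of branched-chain ketoacid oxidation, by 0.78 ± 0.11, while ftcd, of histidine breakdown, fell (−0.90 ± 0.11). The difference of cth was 0.30 with noisy probes left out and 2.02 with 1 probe per gene. That of bhmt was 0.44 without either array that had 26 °C in Cy5 and 1.46 without either that had 34 °C in Cy5. The list passed without the array of 34 °C replicate 1 over 26 °C replicate 3 (adjusted p = 0.0379). Its median was between 0.0027 and 0.0073 without 26 °C replicate 3 or either 34 °C sample. Acute phase, complement and coagulation did not pass either (55 members, median 0.02, camera adjusted p = 0.142), with 12 higher and 4 lower at an unadjusted p under 0.05, and 7 risen and 2 fallen adjusted over the list alone. The complement gene c8g rose by 1.85 ± 0.13, the pentraxin gene apcs by 1.76 ± 0.29, hamp (hepcidin, the iron hormone) by 1.49 ± 0.26 and the heme carrier gene hpxa by 1.25 ± 0.22. The coagulation genes f5 and kng1 rose by 0.74 ± 0.08 and 0.96 ± 0.10, plg (plasminogen) by 0.42 ± 0.07, and f9a and ambp fell (−0.91 ± 0.09 and −0.43 ± 0.07). With noisy probes left out f5 differed by 0.24, and without either array that had 34 °C in Cy5 f9a and ambp differed by −0.60 and −0.17. Without either that had 26 °C in Cy5 ambp differed by −0.68. The acute phase list passed without 34 °C replicate 1 (median 0.18, adjusted p = 9.10e-05), with noisy probes left out (adjusted p = 0.0164) and without either array that had 34 °C in Cy5 (median 0.15, adjusted p = 0.00136 and 0.0169). Its median turned to −0.10 without 34 °C replicate 2 (adjusted p = 0.478) and to −0.02 without 26 °C replicate 3 (adjusted p = 0.567), and was 0.05 without 26 °C replicate 2.

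Targets of growth hormone, insulin-like growth factor, thyroid hormone and glucocorticoids did not shift as a list (43 members, 7 higher and 5 lower, camera adjusted p = 0.236). Adjusted over the list alone, fkbp5 and cebpd, both induced by glucocorticoids, and the transcription factor gene foxo3b rose (0.95 ± 0.07, 0.78 ± 0.07 and 0.63 ± 0.07, the last 1.18 with 1 probe per gene), and the growth factor gene igf2a fell (−1.44 ± 0.18). Cytochromes P450, UDP-glucuronosyl and sulfotransferases did not pass (89 members, 2 higher and 7 lower, camera adjusted p = 0.326), while cyp2k6 and cyp4v2a fell adjusted over the list alone (−2.36 ± 0.25 and −1.30 ± 0.06). That list passed as lower without 34 °C replicate 2 (median −0.10, adjusted p = 6.29e-05). Its median was 0.05 without 34 °C replicate 1 (adjusted p = 0.0847). Bile acid synthesis and lipoproteins did not pass (31 members, 4 higher and 2 lower, camera adjusted p = 0.505), but did without 34 °C replicate 1 (adjusted p = 0.0268). In it lpla (lipoprotein lipase) rose by 0.65 ± 0.06, and lipca (hepatic lipase) and nr1h4 (the bile acid receptor) fell (−1.66 ± 0.18 and −0.65 ± 0.08), each adjusted over the list alone. The gene lpla differed by 0.29 with noisy probes left out and by 1.04 with 1 probe per gene.

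The circadian clock list did not pass (36 members, 5 higher and 5 lower, camera adjusted p = 0.278), and its genes tefa, nfil3-6 and bhlhe40 differed by 0.95 ± 0.19, 0.79 ± 0.17 and −1.02 ± 0.22, the last by −0.59 without either array that had 34 °C in Cy5. The hypoxia response (38 members, 3 higher and 0 lower, camera adjusted p = 0.0868) was led by p4ha2, a collagen prolyl hydroxylase (1.39 ± 0.19, or 2.36 with 1 probe per gene), and passed without either array that had 34 °C in Cy5 (adjusted p = 0.00578 and 0.0169). In the antioxidant and glutathione list (56 members, 4 higher and 8 lower, camera adjusted p = 0.507), catalase (cat) differed by −0.81 ± 0.11 and the heme oxygenase gene hmox1b by 0.86 ± 0.14. The difference of cat was −0.35 without either array that had 34 °C in Cy5 and −1.27 without either that had 26 °C in Cy5. The proteasome list (55 members, 5 higher and 4 lower, camera adjusted p = 0.721) held psmd7 at 0.52 ± 0.05 and psmf1, an inhibitor of the proteasome, at −0.45 ± 0.07 (−0.75 with 1 probe per gene).

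Hepatocyte identity genes did not shift as a list (23 members, 4 higher and 4 lower, median −0.05, camera adjusted p = 0.721). Among them nr5a5, a nuclear receptor, rose adjusted over the list alone (0.87 ± 0.09), and the liver fatty acid carrier gene fabp10a and the transcription factor gene foxa1 differed by 0.65 ± 0.16 and −0.65 ± 0.12 (foxa1 by −0.99 with 1 probe per gene). The list's median was −0.18 without 34 °C replicate 2 and −0.09 without 26 °C replicate 3, and turned to 0.07 without 34 °C replicate 1 and to 0.05 without 26 °C replicate 2. Intestine markers had a median difference of 0.42 over 19 genes (1 higher and 2 lower, camera adjusted p = 0.674), which turned to −0.57 without 34 °C replicate 2 (adjusted p = 9.38e-04) and to −0.08 without 26 °C replicate 2 (adjusted p = 0.65). It was 1.51 without 34 °C replicate 1 (adjusted p = 6.85e-05) and 0.97 without 26 °C replicate 3 (adjusted p = 0.317). The phospholipase gene pla2g12b of that list fell adjusted over the list alone (−1.74 ± 0.21). Pancreas markers had a median of −0.02 over 32 genes (0 higher and 1 lower, camera adjusted p = 0.685) and passed as lower without 34 °C replicate 2 (median −0.17, adjusted p = 0.00104). Their median was 0.10 without 34 °C replicate 1 (adjusted p = 0.164), −0.07 without 26 °C replicate 2 (adjusted p = 0.613) and 0.00056 without 26 °C replicate 3 (adjusted p = 0.846). Leukocyte markers had a median of 0.02 over 31 genes (2 higher and 0 lower, camera adjusted p = 0.278) and passed as higher without 34 °C replicate 1 (median 0.08, adjusted p = 0.0308). Their median was −0.02 without 34 °C replicate 2 (adjusted p = 0.74) and −0.0073 without 26 °C replicate 2 (adjusted p = 0.968), and it was 0.05 without 26 °C replicate 3 (adjusted p = 0.0806). Muscle and connective tissue markers rose as a list (30 members, 1 higher and 0 lower, median 0.09, camera adjusted p = 0.0215, adjusted p = 0.75 with an estimated correlation), with the myosin light chain gene mylpfa at 0.48 ± 0.14 (0.32 without 34 °C replicate 2 and 0.80 with 1 probe per gene). That call was lost without 26 °C replicate 3 (median 0.10, adjusted p = 0.0955), without 34 °C replicate 2 (median 0.02, adjusted p = 0.819) and without either array that had 34 °C in Cy5 (median 0.08, adjusted p = 0.102 and 0.0693). Without 34 °C replicate 1 the median was 0.17. Erythrocyte markers fell as a list (16 members, 0 higher and 3 lower, median −0.04, camera adjusted p = 0.0496, adjusted p = 0.69 with an estimated correlation), and nt5c2l1 fell adjusted over the list alone (−0.78 ± 0.10). This call was lost in 10 of 15 settings, among them without 26 °C replicate 2, 34 °C replicate 1 or 34 °C replicate 2 (medians −0.03, −0.06 and −0.04, adjusted p = 0.117, 0.178 and 0.0735) and without any 1 of the 4 arrays (0.096, 0.0887, 0.066 and 0.0911).

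**Figure D3:**
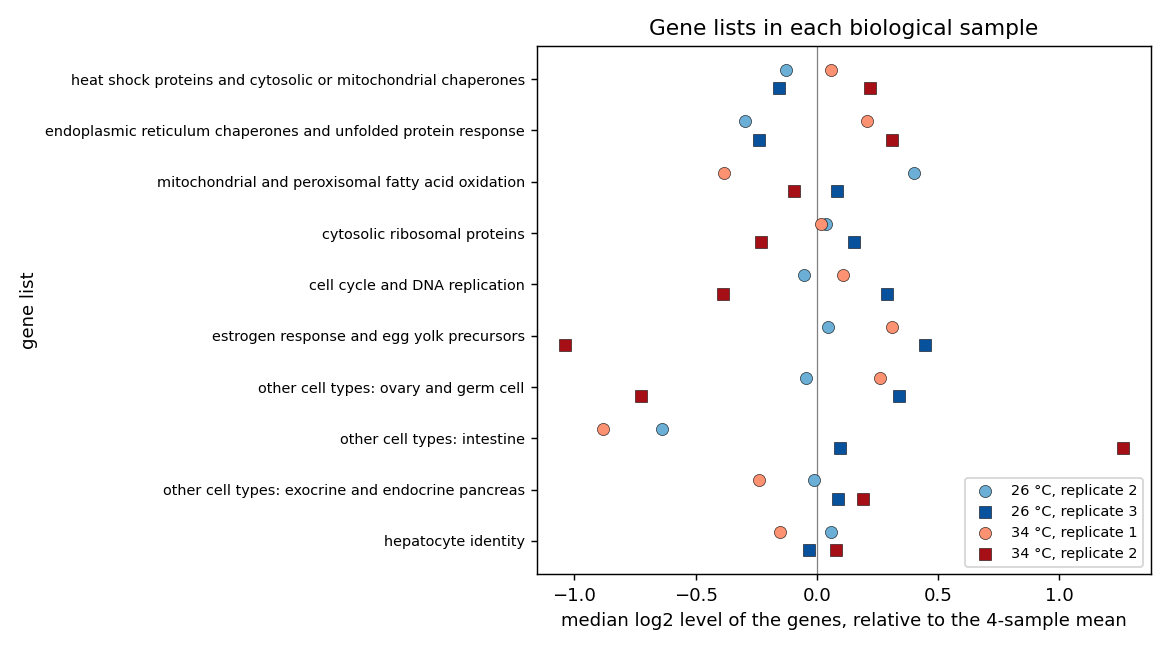
Median log2 level of 10 gene lists (rows) in each of the 4 biological samples (symbols), relative to the mean of the 4 samples. The heat shock list lay at −0.13 and −0.16 at 26 °C and at 0.06 and 0.22 at 34 °C, while the intestine markers lay at 1.26 in 34 °C replicate 2 and between −0.88 and 0.10 in the other 3 samples.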

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

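The call of 0 genes at adjusted p 0.05 held with samples as units under every alternative run, and changed with the 4 arrays as units: 148 genes with a dye term (1394 higher and 1153 lower at an unadjusted p under 0.05) and 538 without (1466 and 1172). By construction its squared standard error with the dye term is smaller by a factor of 2, as arrays sharing a sample count as independent. Counting probes gave 1765 higher and 1321 lower. Leaving out a sample or array, the higher genes ranged from 489 to 1491 and the lower from 284 to 1211, and the lists past adjusted p 0.05 from 10 to 17. With 1 sample left in a group, it is assumed to vary like the other group. Leaving out an array leaves the temperature difference on the 2 arrays of the other orientation, where the dye effect no longer cancels.

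The heat shock, endoplasmic reticulum and fatty acid oxidation lists passed in 15 of 15 alternatives that kept the preset correlation. With an estimated correlation, which also leaves the test 2 degrees of freedom, 0 lists passed. The other lists past the threshold each lost the call or turned in 1 to 10 of the 15. Over left-out samples and arrays, the median ranged from −0.034 to 0.114 for oxidative phosphorylation, from −1.27 to 0.17 for the estrogen list, from −0.57 to 1.51 for intestine markers and from −0.89 to 0.11 for ovary markers; for oxidative phosphorylation camera's direction also turned without the array of 34 °C replicate 1 over 26 °C replicate 3 (median 0.0029). The turns without 34 °C replicate 2 follow its own levels of these genes, and the cause was otherwise not tested. Of 1909 values of named genes under the alternatives, 1903 kept their direction, and the 6 that turned belong to hsp90aa1.1 (−0.0054), cirbpb (−0.09 and −0.27) and ddx4 (0.01). The direction was largely fixed by the selection, as 122 of the 129 named genes had 1 sign on all 4 arrays. Adjusted p 0.05 was passed by 112 values, all from fits with arrays as units, since 0 genes passed with samples as units. Scaling moved the median of all genes from −0.0033 to −0.0018. The difference of 54 of the 129 named genes moved by over 1.5 times with its sign kept in at least 1 setting, 25 of them with a sample left out and 23 with an array left out. The alternative for missing values was not run, as none were missing. No paired analysis was possible because the groups share only 1 replicate number. Signal over background is unknown, so what dim probes limit could not be read.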

Other observations

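The genes farthest from the mean of the other 3 samples, chosen after their values were seen, are given as the 4 highest and 4 lowest of each sample with clone identifiers left out. In 34 °C replicate 2 chia.1 (an acidic chitinase), hsp70.3, slc13a2 (a carboxylate carrier) and cyp46a1.1 (a cytochrome P450) were higher by 4.67, 4.54, 4.42 and 3.85. In it vtg3, nots, vtg2 and vtg4 were lower, at −3.68, −2.66, −2.28 and −2.12. In 34 °C replicate 1 aldoab, junbb (an early stress gene), igfbp1a (a binding protein of insulin-like growth factor) and gadd45ga (an early stress gene) were higher by 2.56, 2.33, 2.32 and 2.26. In it chia.2, chia.3, slc13a2 and apoea (an apolipoprotein) were lower, at −3.87, −3.41, −3.06 and −3.04. In 26 °C replicate 2 vtg3, rab1aa, elovl2 and rdh8a were higher by 2.12, 1.87, 1.81 and 1.74. In it chia.1, cyp46a1.1, hsp90aa1.2 and hsp70.3 were lower, at −2.66, −2.58, −2.34 and −2.33. In 26 °C replicate 3 vtg3, apoea, chia.3 and fabp1b.1 (a fatty acid binding protein) were higher by 2.31, 2.07, 2.07 and 1.93. In it hsp70.3, hsp90aa1.2, cbln6 and hsp70l were lower, at −2.69, −2.28, −1.98 and −1.85. These are values of 1 sample each, and neither the genes nor any group of them was tested.

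The tests of ovary, intestine and muscle carry-over and of a larger response in 34 °C replicate 2 were chosen only after the results were seen. The others were written before. Standard errors (SE) in all these tests come from resampling genes, which are not replicates, and leave out the spread between biological samples. A value for a single 34 °C replicate rests on 1 sample. A first intestine test for the heat shock list set the median gap of heat shock members between 26 °C replicates 3 and 2 (−0.07) against a bound of 0.04 scaled from their gap between the 34 °C samples, and was replaced after its value was seen because it took the heat shock level of intestine as equal at both temperatures. The ovary test and the second intestine test of the heat shock list first used 26 °C replicate 2 alone (−1.38 and 0.171) and were then taken against the mean of the 26 °C samples, also after these values were seen.

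The rise of endoplasmic reticulum chaperones at 34 °C (median 0.49 over 44 genes) could come from secretory cells of other kinds in the dissected tissue. Pancreas carry-over is argued against: the 32 pancreas markers, 1 of which the chaperone list shares, had a median difference of −0.0157, below a bound of 0.244 (0.5 times the list's median) by over 2 bootstrap standard errors of 0.0987, though their median range over samples was 0.705. Intestine carry-over is argued against for 34 °C replicate 1, where the list's median was 0.467 above the 26 °C mean (SE 0.15) while the 19 intestine markers lay at −0.57, and stays open in 34 °C replicate 2, with these markers at 1.51. For leukocytes and for muscle and connective tissue, the 31 and 30 markers had medians of 0.0158 and 0.0941 under the same bound, but their ranges over samples, 0.227 and 0.246, were close to the 0.196 of all genes, so dim probes could hide a change and both stay open. A response of liver cells to temperature is a hypothesis that cannot be told apart from larger shares of these cells here.

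The 5 vitellogenins had a median difference of −1.96, and some other genes, such as elovl2 and cyp2k6 (−2.40 and −2.36), differed as far. A lower share of hepatocytes as the whole cause is argued against. The median over 23 hepatocyte identity genes was −0.0546, against a bound of −0.978 (SE 0.252). After the arrays were scaled, the vitellogenin median was −1.97 (SE 0.212). The scaling evened out the arrays' median absolute ratios, and the median absolute deviations did not set 34 °C replicate 2 apart. They were 0.127 and 0.150 on its arrays and 0.118 and 0.151 on those of replicate 1. Wider ratios on the arrays of 34 °C replicate 2 therefore stay open for the size of the fall in that sample. They cannot account for the fall in 34 °C replicate 1 (−1.35 from the 26 °C mean), which is solved from the other 2 arrays alone. Less ovary tissue is argued against for 34 °C replicate 1, where the vitellogenins lay at −1.35 (SE 0.343) from the 26 °C mean while the 30 oocyte markers lay at 0.11. In 34 °C replicate 2 both moved down (−2.58 and −0.89), so carry-over stays open for part of its fall. The sex and spawning state of the fish are not in the labels, and a difference in either stays open beside temperature, untested.

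The heat shock list was higher at 34 °C. Its 25 higher members lay 0.186 (median) further up in 34 °C replicate 2 than in replicate 1, with 17 of 25 above 0. These 25 had an unadjusted p under 0.05, whose error includes the gap between the 34 °C samples. Members with wide gaps of either sign were thus partly left out, such as dnajb1b (−0.03 and 1.27 in replicates 1 and 2) and hspa12b (0.43 and −0.09). The gap and the tests on it hold for the chosen members only. Intestine carry-over is argued against for 34 °C replicate 1, where the list's median was 0.171 above the 26 °C mean (SE 0.0761) while the 19 intestine markers lay at −0.57; in 34 °C replicate 2, with these markers at 1.51, it stays open. For the gap itself, scaling the arrays left 0.160, above its bound of 0.093 by less than 2 bootstrap standard errors of 0.0537. Wider ratios on the arrays of 34 °C replicate 2 cannot be excluded. The scaling could not decide this either way, as the spread it evened out did not set those arrays apart. A larger response of every temperature-dependent gene cannot be told apart either, as the gap's share of the temperature difference in endoplasmic reticulum members minus that in heat shock members was −0.136 with an SE of 0.141. The state of the fish behind each sample may also differ and was not tested.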
